A study of Mus musculus with 2 samples.

How the data were processed

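MicroRNA reads were measured in the hearts of 2 female B6CASTF1/J mice, an F1 hybrid of the C57BL/6J and CAST/EiJ strains, at 25 days of age. The labels give the animals as biological replicates 1 and 2, and their descriptions number the animals separately, although both samples carry the same donor identifier. The SDs and the spread between animals rest on that reading. The age field gives 25 days, while the unit in a free-text label differs. Both libraries belong to 1 group, and no control or second group was analysed here, so no contrast between groups was tested. MicroRNA-seq counts short RNA fragments, and a hairpin is the folded precursor from which mature microRNAs are cut. The labels give an upper size limit for the fragments and point to a multiplexed small RNA protocol.

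The deposited tables hold raw counts of reads per annotated hairpin, without normalization, in columns that count reads on either strand, on the strand of the hairpin and on the opposite strand. Reads were placed on the mm10 assembly of the mouse genome with GENCODE annotation release M21, per the file headers of the text notes deposited with the tables. The aligner, the counting program and their settings were not given in the sources used here. The tables also hold rows for unmapped reads, reads matching several places, reads in no hairpin and reads that could belong to more than 1 hairpin. The layout is that of a counter that assigns only reads with a single best place, so reads shared by identical hairpins would be missing from the hairpin counts. Mature arms were not separated in these tables, so each value describes a whole hairpin.

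All 2202 identifiers in the tables matched GENCODE M21, which gave the symbols, coordinates and overlapping genes. The column for the strand of the hairpin was used, because it had the larger sum of the 2 stranded columns. Rows that name no hairpin stayed out of library totals. In replicate 1, 38.5% of reads matched several places, 14.1% were unmapped and 6.48% lay in no hairpin. In replicate 2, these shares were 41.6%, 11.5% and 5.64%. Hairpin counts summed to 2050498 in replicate 1 and 2661090 in replicate 2. CPM, the count of a hairpin over the library sum on the usual scale, was computed from these sums, and a floor of 3 counts equals 1.46 CPM in replicate 1 and 1.13 CPM in replicate 2. Intervals are 95% Wilson or exact binomial intervals. Intervals and floors cover counting error only, because PCR copies of a molecule were not told apart.

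A hairpin was called detected with at least 10 counts in both libraries. Fixed lists of microRNAs, 20 in all, covered striated muscle, endothelial cells, smooth muscle cells and pericytes, fibroblasts, erythroid cells, leukocytes, neurons, epithelium, the liver with kidney and gut, ciliated cells and pluripotent cells. They also covered the Dlk1-Dio3 and Sfmbt2 clusters, other imprinted hosts, and the let-7, miR-30, miR-29, miR-15, miR-17-92 and miR-23-27-24 families. The share of a list is its percent of all hairpin counts.

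The libraries were compared over the 326 hairpins with at least 10 counts in at least 1 of them. Scaling used TMM factors from edgeR 4.0.16 in R 4.3.3. Each hairpin was tested with an exact two-sided binomial test of its 2 counts against the ratio of effective library sizes, with Benjamini-Hochberg adjustment. That test compares these libraries and not conditions, and 2 samples cannot give an exact two-sided p below 0.5 for any difference between animals. The biological coefficient of variation (BCV), the spread between animals beyond counting error, came from the common dispersion of edgeR with an intercept-only design. Log2 ratios are of replicate 2 over replicate 1 on TMM-scaled CPM plus 1, so they differ from ratios of the CPM given in the text. For lists with at least 3 tested hairpins, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression. Correlations between libraries were taken across hairpins, which are not independent replicates.

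Before the data were examined, the lists, the tests and a rule for the hairpins to be named were fixed. The rule took the 15 hairpins with the highest mean CPM, up to 3 of the highest in each list with at least 10 counts in both libraries, and Mir208a, Mir208b and Mir499. It also took the 5 highest and 5 lowest log2 ratios among hairpins past the binomial test with at least 100 counts in at least 1 library. Other hairpins named in the text were chosen after their values were seen. Alternatives fixed in advance were the unstranded column, other count minimums, totals and pseudocounts, and DESeq2 1.42.0 size factors and dispersions. They also covered scaling by total count, leaving out hairpins with a locus number in the symbol, and leaving out each replicate. A further alternative left out the 10 highest hairpins before scaling, which also took them out of the tests, lists and library totals. Adding Mir92-1 and Mir92-2 to the miR-17-92 list, whose fixed name for them matched no symbol, was chosen after seeing the data. Tables were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots with matplotlib 3.10.9.

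The comparison was tested on simulated data drawn from the means and sizes of these libraries, with 200 hairpins changed. Except where a BCV is given, the draws held counting error only, which is the noise model of the binomial test. The rates therefore do not cover spread between animals or noise from PCR copies. Of 97 testable hairpins changed 2-fold, 83 were recovered, and of 97 changed 1.5-fold, 59 were recovered. Of 128 unchanged hairpins, 2 were called. Libraries simulated with no change gave 0 calls among 318 hairpins by the binomial test, with 11 at an unadjusted p under 0.05. Counts simulated with a BCV of 0.4 gave an estimate of 0.402. In the libraries without a change, 1 of 17 lists lay outside the central 95% of matched random lists.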

Results

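MicroRNA hairpins were counted in heart tissue from 2 female B6CASTF1/J mice aged 25 days, each a biological replicate of 1 group. Replicate 1 held 5005996 reads, of which 2050498 (41.0%) were assigned to hairpins. Replicate 2 held 6452546 reads, of which 2661090 (41.2%) were assigned. Of 2202 annotated hairpins, 288 had at least 10 counts in both libraries, and 559 in replicate 1 and 570 in replicate 2 had at least 1 count. The design implies a description of the heart at this age and a comparison of the 2 animals, and errors are SD with n = 2 unless stated. Coordinates are those of mm10.

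Among the reads assigned to hairpins, Mir378a had the highest counts in both libraries and reached 179927 ± 29610 CPM. Reads matching several places, 38.5% and 41.6% of the libraries, entered no hairpin count. It lies on chromosome 18 from 61397835 to 61397900, in an intron of Ppargc1b, a coactivator gene of mitochondrial metabolism. Mir126a, the endothelial microRNA located within Egfl7 on chromosome 2 from 26591357 to 26591429, was second by mean with 8.45% ± 3.33 of the counts. Mirlet7i, Mir23b and Mirlet7g came next with 71032 ± 4809, 66528 ± 5779 and 60059 ± 980 CPM. The 10 highest hairpins together held 68.5% ± 4.60 of the counts, 65.2% in replicate 1 and 71.7% in replicate 2.

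The rest of the 15 highest hairpins mixed broadly expressed and cell type microRNAs. Mir23a reached 59073 ± 17895 CPM and Mirlet7b 51103 ± 2693 CPM. Mir99a had 39856 ± 18094 CPM. Mir139, in an intron of the phosphodiesterase gene Pde2a on chromosome 7 from 101475376 to 101475443, had 37155 ± 5357 CPM. Mir143, a microRNA of smooth muscle on chromosome 18 from 61649196 to 61649258, had 35311 ± 10173 CPM. Mir26b, in an intron of Ctdsp1, had 26099 CPM and Mir22 had 25685 CPM, with SDs of 3336 and 20872 CPM. Mir99b, Mirlet7d and Mir30d closed the group at 20451, 20429 and 18684 CPM, with SDs of 803, 91.1 and 9278 CPM. In the counts taken without regard to strand, Mir378a stood at 0 and Mir126a at 12.1 CPM.

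The let-7 family, regulators of cell growth and differentiation, held 21.9% ± 0.0935 of the counts, the largest share of the 20 lists in both libraries. All 12 of its hairpins were detected, led by Mirlet7i, Mirlet7g and Mirlet7b. The miR-23-27-24 clusters held 13.3% ± 2.23, nearly all of it from Mir23b and Mir23a. Mir24-1 and Mir24-2 share 28 nt, Mirlet7a-1 and Mirlet7a-2 23 nt, Mirlet7c-1 and Mirlet7c-2 23 nt, and Mirlet7f-1 and Mirlet7f-2 22 nt. Reads shared by such loci would enter no hairpin count, so the order within these lists holds for counted reads only. The miR-30 family held 3.61% ± 1.41, led by Mir30d, Mir30a and Mir30e. The miR-15 family held 1.39% ± 0.744, the miR-17-92 family 0.691% ± 0.0612 and the miR-29 family 0.446% ± 0.170. The miR-17-92 list as fixed missed Mir92-1 (4070 and 4380 counts) and Mir92-2, and with both its share was 0.881% ± 0.0854. Mir322 (4391 ± 1012 CPM), Mir93 (4031 ± 40.3 CPM) and Mir29a (4229 ± 1612 CPM) had the highest means of these families, although Mir195a and Mir15b exceeded Mir322 in replicate 1.

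The striated muscle list held 0.641% ± 0.270 of the counts, and its counted reads came mostly from hairpins within myosin genes. Its share was 0.450% in replicate 1 (95% Wilson interval 0.441 to 0.459) and 0.831% in replicate 2 (0.821 to 0.842), with ranks of 12 and 7 among the 20 lists. Of its 11 hairpins, 4 carry a locus number, and reads shared between loci would enter no hairpin count. The share and ranks therefore hold for counted reads only and cannot show how abundant muscle microRNAs were. Mir208a, in an intron of Myh6, the main adult ventricular myosin gene of the mouse, had 3741 ± 2999 CPM. Mir499, in an intron of Myh7b, had 2473 ± 220 CPM. Mir208b, in an intron of Myh7, the fetal ventricular myosin gene, had 151 ± 55.9 CPM. Mir208a lies on chromosome 14 from 54949060 to 54949142 and Mir208b from 54975700 to 54975776.

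Mir208a supplied most of the counts of the Myh6 and Myh7 pair in both hearts. It made up 89.5% of Mir208a plus Mir208b in replicate 1 (exact interval 88.4 to 90.4) and 98.1% in replicate 2 (97.9 to 98.3), a mean of 93.8% ± 6.12. Of the 11 muscle hairpins, 4 were detected. Mir1a-2, one of the loci of the muscle microRNA miR-1, had 94 counts in replicate 1 and 31 in replicate 2. Mir1a-1 had 3 and 1 counts, Mir133a-1 had 3 and 8, Mir133a-2 had 8 and 7, Mir133b had 8 and 8, and Mir206 had 5 and 7. Mir1a and Mir133a hairpins share 28 to 31 nt with a second locus, and reads matching several places numbered 0.939 per hairpin count in replicate 1 and 1.01 in replicate 2.

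Among the other cell types of the heart, the endothelial and smooth muscle lists held the largest shares of counted reads. The endothelial list held 8.45% ± 3.33, almost all Mir126a, and 0.00121% in the unstranded column. Mir143 and Mir145a, which mark smooth muscle cells and pericytes, brought their list to 3.88% ± 1.34. The fibroblast list held 0.433% ± 0.270, with Mir214 at 2380 ± 2647 CPM and Mir21a at 1939 ± 50.3 CPM. Of its 5 hairpins, 2 carry a locus number, Mir199a-1 (0 and 0 counts) and Mir199a-2 (9 and 6). The endothelial and smooth muscle lists have 0 such hairpins. Reads shared between loci would enter no hairpin count, so the fibroblast share may be too low. The leukocyte list held 0.609% ± 0.00389, mostly Mir155, Mir150 and Mir342. The erythroid list held 0.133% ± 0.0646, and its members Mir486, Mir451a and Mir144 had 2010, 982 and 664 counts in replicate 1 and 1545, 550 and 218 in replicate 2. In the unstranded column, where Mir486 and Mir451a stood at 0, the erythroid share was 0.0288%.

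Few of the counted reads fell on microRNAs of other tissues. The epithelial list held 0.0395% ± 0.00184, led by Mir200c, and the liver, kidney and gut list 0.0193% ± 0.00616. The ciliated cell, pluripotent cell and neuronal lists held 0.00686% ± 0.00177, 0.00367% ± 0.00374 and 0.00313% ± 0.000628. The pluripotent cell share was 0.00109% without hairpins under 10 counts in either library, and the neuronal share 0.00159% without hairpins that carry a locus number. Of the 13 neuronal hairpins, 10 carry a locus number and 7 had 0 counts in both libraries. Reads shared between loci would enter no hairpin count, so the neuronal share cannot show how rare these microRNAs were. The imprinted Dlk1-Dio3 cluster held 0.550% ± 0.0826, with 37 of 55 hairpins detected and Mir127 the highest at 2218 ± 754 CPM. The Sfmbt2 repeat cluster held 0.114% ± 0.0163, with 7 of 79 hairpins detected and Mir467d the highest. Of the 79, 70 had 0 counts in both libraries and 44 carry a locus number, so reads shared between copies may be missing from this share. The list of other imprinted hosts held 0.175% ± 0.0317, most of it Mir335 in an intron of Mest.

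**Figure D1:**
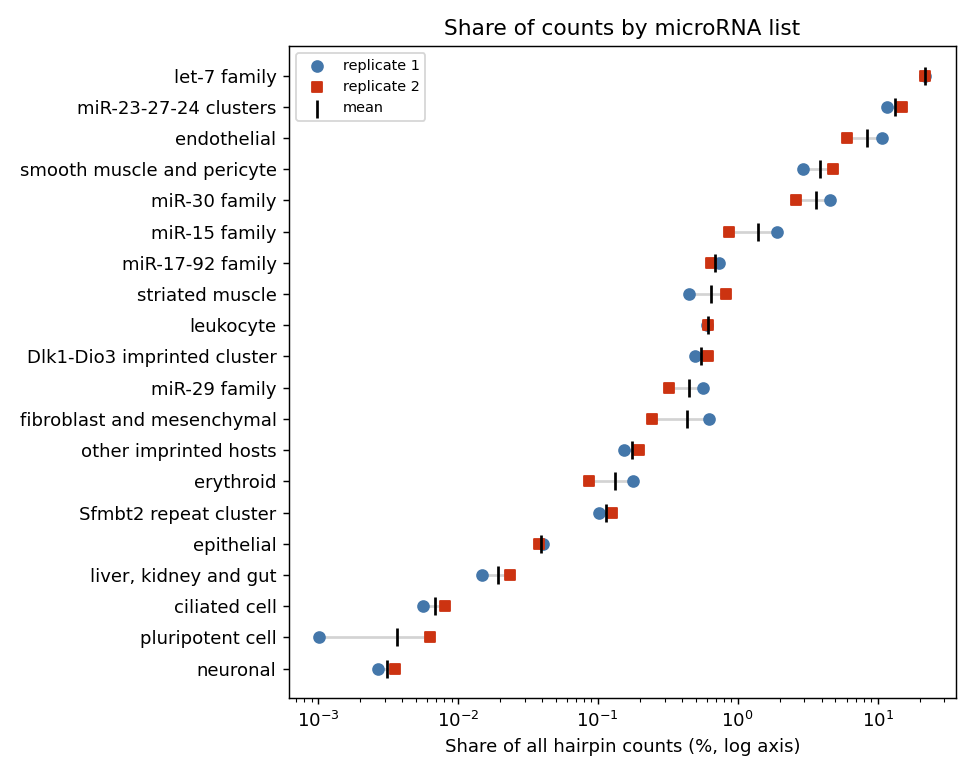
Share of all hairpin counts (percent, log axis) for the 20 microRNA lists, with points for replicates 1 and 2 and a bar at their mean. The let-7 family was highest at 21.9%, and the striated muscle list lay at 0.450% and 0.831%. Reads matching several places entered no share.

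The comparison of the 2 animals asked how far microRNA levels varied between hearts of 1 strain, sex and age. Among all tested hairpins past 100 counts, the liver microRNA Mir122 had the largest excess in replicate 2, with 47 counts against 540 (log2 ratio 3.32, adjusted exact binomial p = 5.59e-96). Mir145a (2.46), Mir140 (2.09), Mir208a (2.08) and Mir351 (1.79) followed. Mir205, a microRNA of epithelium, was lower in replicate 2, with 238 counts against 4 (log2 ratio -5.36, adjusted exact binomial p = 7.35e-70). Mir301 (-3.10), Mir214 (-2.83), Mir195a (-2.78) and Mir215 (-2.50) were also lower. With TMM scaling, Mir499 did not pass the test (log2 ratio 0.05, adjusted exact binomial p = 0.110), while Mir208b was lower (log2 ratio -0.54, adjusted exact binomial p = 2.50e-06). Over the library sums, Mir499 went the other way, with 2629 CPM in replicate 1 and 2317 CPM in replicate 2.

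Levels ranked similarly in both hearts, and many single hairpins still differed by more than the counting error of independent reads. Across 326 hairpins, Pearson's r was 0.958 and Spearman's rho 0.939, and 236 hairpins lay within 2-fold. The exact binomial test called 204 hairpins, 118 higher and 86 lower in replicate 2, and 128 of them differed at least 1.5-fold, 65 higher and 63 lower. The BCV was 0.467. Summed over hairpins, chi-square per degree of freedom was 695, above what counting noise of independent reads gives, and the libraries were not merged. PCR copies were not told apart, so this value cannot separate their noise from a difference between the animals. That the libraries come from 2 animals rests on the labels. Scaling by total count moved the median log2 ratio from 0.09 to -0.14 and gave 76 higher and 117 lower. Leaving the 10 highest hairpins out of the data, with 316 tested, gave 87 and 97. More hairpins were lower than higher in 5 of 7 alternatives, and in 7 of 7 among those differing at least 1.5-fold (44 higher and 84 lower by total count).

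**Figure D2:**
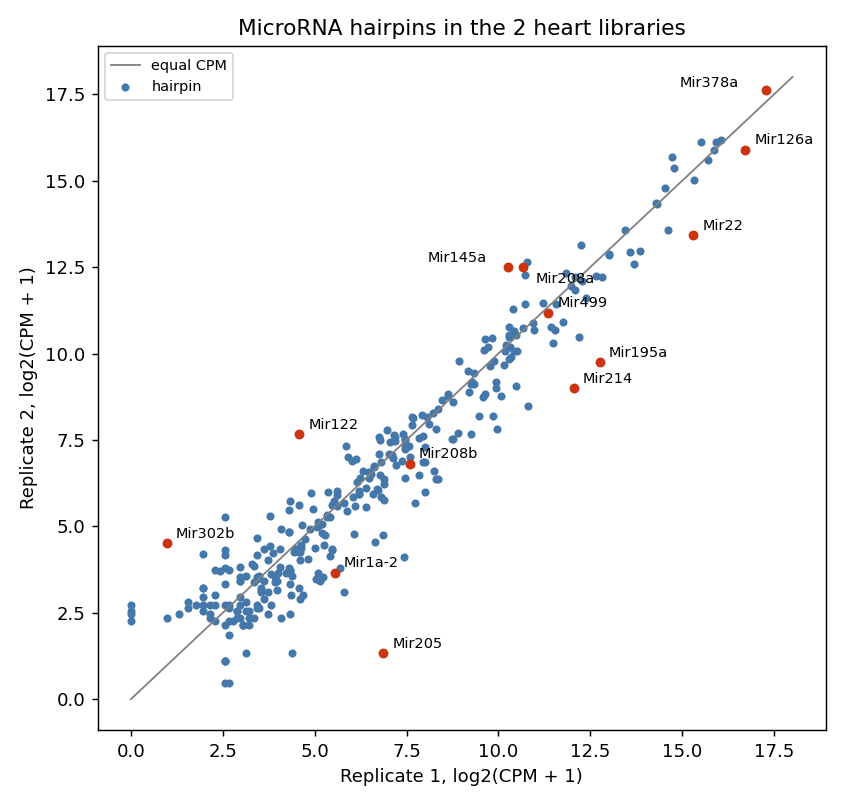
Each point is 1 hairpin, with log2(CPM + 1) in replicate 1 on the x axis and in replicate 2 on the y axis, and the line marks equal CPM. Pearson's r across the 326 hairpins was 0.958, and labelled hairpins such as Mir122 (47 and 540 counts) and Mir205 (238 and 4 counts) lie far from the line.

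By list, the miR-15 family, which restrains the cell cycle, was lower in replicate 2 in 6 of its 7 tested hairpins. Its median log2 ratio was -1.47, below all 10000 matched random lists. Mir195a had 14176 and 2283 counts and Mir15b 9521 and 3806, while Mir322 was higher with 7536 and 13588. The 6 lower hairpins lie in pairs of neighbours within 10 kb: Mir15b with Mir16-2, Mir15a with Mir16-1, and Mir195a with Mir497. Mir16-1 and Mir16-2 also share 23 nt. The random lists did not copy such pairs. Relative to the median of all hairpins (0.09), 5 of 17 lists lay outside the central 95% of random lists, where 0.85 would be outside for lists of unrelated hairpins. Distant hairpins sharing 14 nt or more had correlated ratios (r = 0.494, permutation p = 0.000300), and the random lists did not copy this. The correlation was 0.792 in the 18 pairs sharing 20 nt or more and 0.298 in the 38 pairs sharing 14 to 19 nt. The 14 nt cutoff was picked after 4 cutoffs had been looked at.

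The other lists outside that range were mostly higher in replicate 2. The leukocyte list had a median of 0.76 (percentile 99.8), with 4 hairpins higher, Mir150 among them at 2753 and 6677 counts, and Mir155 lower at 6113 and 4344. Its share of counts was 0.607% and 0.612% in the 2 libraries, and in the unstranded column the list fell inside the range (percentile 97.3). In the Dlk1-Dio3 cluster, 30 of 42 tested hairpins had ratios above 0 (median 0.37, percentile 99.7, with a median of 0.16 by total count). Of these 42, 18 were higher and 4 lower by the exact binomial test over all hairpins, and 14 and 4 adjusted over the list alone. Mir127 had 3456 and 7321 counts and Mir411 1182 and 1911. In the pluripotent cell list, the 4 tested hairpins were all of the Mir302 cluster and were higher, with Mir302d at 10 and 45 counts. The other 3 had under 10 counts in replicate 1, and hairpins of the Mir290 cluster had at most 4 counts. Their median was 2.62, or 2.11 with Mir302c, at 0 in replicate 1, set to the floor of 3 counts there. It was 1.46 with a pseudocount of 5 CPM, 3.15 with 0.5 CPM and 1.72 with no filter beyond 1 count. With at least 50 counts the list was too small to test. Without the 10 highest hairpins it was 3.38, where library sums were smaller (713456 and 752929) and the pseudocount stood for fewer counts.

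The liver, kidney and gut list had a median of -1.22 (percentile 1.1), with Mir215 and Mir192 lower and Mir122 higher. Its share of counts went the other way, with 0.0149% in replicate 1 and 0.0236% in replicate 2, and with at least 50 counts the list fell inside the range (percentile 4.41). All 3 erythroid hairpins were lower (median -0.98, percentile 6.84), as were all 4 of the miR-29 family (median -0.86, percentile 2.74). All 7 tested hairpins of the Sfmbt2 cluster were higher (median 0.64, percentile 97.2), although some share sequence (48 nt for Mir467c and Mir467e). These 3 lists stayed within the central 95%, except that the Sfmbt2 cluster left it with no filter beyond 1 count (percentile 99.2). Medians of the striated muscle (-0.25), fibroblast (-0.18), neuronal (0.93), epithelial (0.26), miR-30 (-0.14) and miR-17-92 (-0.08) lists also stayed within it. So did let-7 (0.09), miR-23-27-24 (0.12) and other imprinted hosts (0.08), whose medians turned negative with scaling by total count (-0.14, -0.11 and -0.14). The epithelial median was -0.77 with at least 50 counts, and in the unstranded column those of striated muscle and miR-30 were 0.03 and 0.08. The neuronal median was 0.13 with no filter beyond 1 count. That of miR-30 was -0.55 without hairpins that carry a locus number. That of miR-23-27-24 was -0.29 without the 10 highest hairpins, which took Mir23a and Mir23b out of this list.

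**Figure D3:**
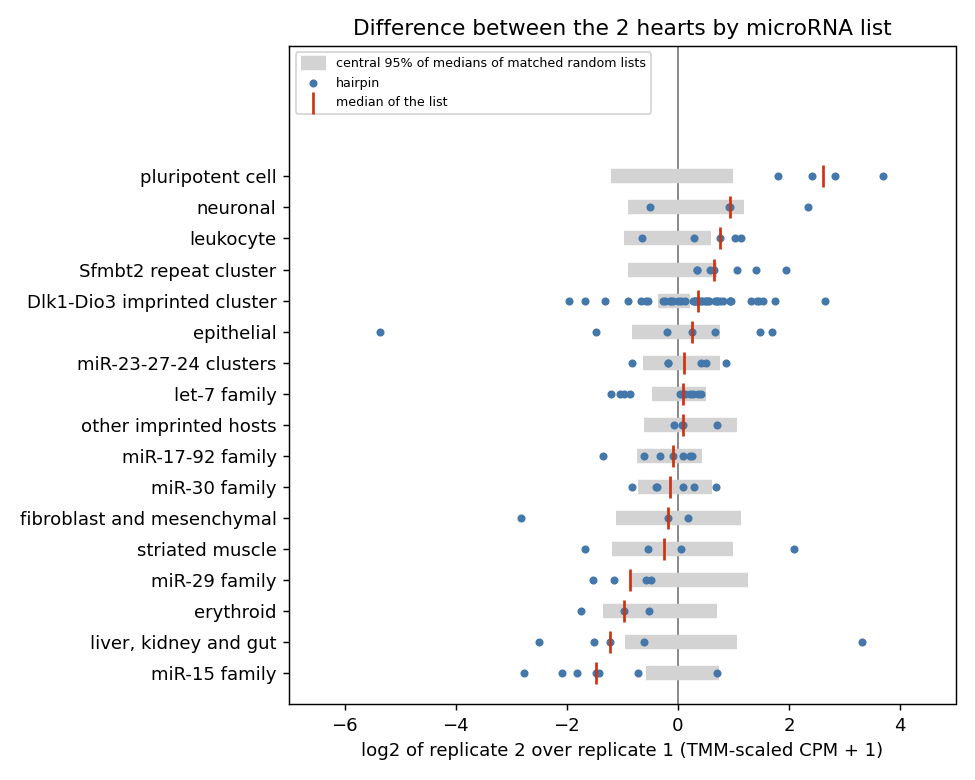
Log2 of replicate 2 over replicate 1 (TMM-scaled CPM + 1) for each tested hairpin (points) of 17 lists, with the list median (vertical mark) and the central 95% of medians of 10000 matched random lists (grey). The miR-15 median of -1.47 and the pluripotent cell median of 2.62 lie outside the grey range.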

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

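All of the tests of explanations in this part were chosen after the result they bear on was seen. Reads matching several places, which enter no hairpin count, numbered 1925044 in replicate 1 and 2686901 in replicate 2. Reads counted as ambiguous without regard to strand numbered 609641 and 768383, against 0 in both libraries in the column for the strand of the hairpin. At the 2138 hairpins with no hairpin on the other strand, the opposite-strand column still held 44 and 43 reads. The reads matching several places and the opposite-strand reads lie outside the main measurement. The ambiguous reads lie inside it, since the column for the strand of the hairpin assigned them. The values above 0 were flagged only because they lie above the 3 counts that a count of 0 allows. That rule does not show that they are unusual.

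Mir1a and Mir133a, known as abundant microRNAs of heart muscle, had at most 94 counts at any of their 4 hairpins. Counting on the wrong strand was argued against, since the highest opposite-strand count of the 4 hairpins was 1. Reads shared between loci may account for the low values, since 4 of the 4 hairpins share at least 20 nt with another hairpin and reads matching several places were about as many as hairpin counts. Sharing alone does not settle it: hairpins sharing 20 nt or more, Mir23a and Mir23b among them, include 71 detected ones and held 29.8% and 36.7% of the counts. This comparison cannot decide either way, since Mir23a and Mir23b share 20 nt, while the Mir1a hairpins share 28 nt and the Mir133a hairpins 31 nt. It stays open where the reads matching several places belong, and no biological explanation was tested.

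Hairpins such as Mir378a, Mir126a, Mir191 and Mirlet7e lost nearly all of their counts in the column taken without regard to strand. A hairpin annotated on the opposite strand is a candidate explanation. Of the 19 hairpins that kept under 10% of their 100 or more counts, 19 have such a partner, against 0 of the 191 that kept theirs. These 19 held 29.7% of the counts in replicate 1 and 28.9% in replicate 2. No biological explanation was tested.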

How the results depend on the processing

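The alternatives were fixed before the data were examined, except adding Mir92-1 and Mir92-2 to the miR-17-92 list, which was chosen after seeing the data. Results past a test or outside the range of random lists were taken as kept when direction and side of the threshold stayed, whatever their size. Other values were kept within 1 SD (of replicates, bootstrap samples or random lists), counts within 1.5 times and the BCV within 10%. Of the values that answer a comparison, 52 were kept and 7 moved, but the balance of higher and lower hairpins turned in 5 of 7 alternatives. With 1 count in both libraries as the minimum, 481 hairpins were detected rather than 288. In the unstranded column, the lists other than striated muscle held 64.5% of the counts rather than 55.7%, because hairpins with an opposite-strand partner left the total. Pearson's r was 0.974 with no filter beyond 1 count, 0.945 with at least 50 counts and 0.967 with a pseudocount of 5 CPM, and Spearman's rho was 0.884 without the filter. With at least 50 counts, 3 of 13 lists lay outside the range of random lists, with fewer lists tested. The cause of the other moves was not tested. Of the remaining values, 251 were kept, 38 moved, 1 passed the threshold (Sfmbt2, no filter) and 2 lost it: the leukocyte median (0.64) in the unstranded column and the liver list (-1.37) with at least 50 counts. The medians of 6 of 17 lists changed sign in some alternative, 0 of them among those outside the range of random lists. The BCV from edgeR ranged from 0.459 to 0.478 when 1 setting was changed at a time. The square root of the median DESeq2 dispersion, a different measure, was 0.497 with the main settings. It was 1.11 with no filter beyond 1 count and 0.450 with at least 50 counts. Leaving out a replicate gives the other library's value, always within 1 SD of their mean, so it tests nothing here and was not counted. No paired analysis was possible because there is 1 group. With 2 animals, depth limits low lists such as the pluripotent cell and neuronal lists, whose hairpins mostly lay under 100 counts.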

Other observations

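Some hairpins of 1 genomic cluster moved apart between the hearts, in examples picked after their values were seen. The median absolute difference in log2 ratio was 0.58 between neighbours and 0.80 over all pairs, and the ratios of neighbours had a correlation of 0.159 (permutation p = 0.110). Mir99a was higher in replicate 2 (log2 ratio 1.19), while its neighbour Mirlet7c-1 was lower (-0.98). Mir100 and its neighbour Mirlet7a-2 showed the same contrast (1.13 and -0.86). Mir23a was higher (0.86) and its neighbour Mir24-2 lower (-0.83). Each of these lower neighbours shares sequence with another locus: Mirlet7c-1 with Mirlet7c-2 (23 nt), Mirlet7a-2 with Mirlet7a-1 (23 nt) and Mir24-2 with Mir24-1 (28 nt). Since reads shared by such loci would enter no hairpin count, the ratios of these lower neighbours hold for counted reads only. On the X chromosome, Mir322 and Mir351 were both higher. Mir302a, Mir302b and Mir302c of the pluripotent cell list had 6, 2 and 0 counts in replicate 1 and 46, 58 and 15 in replicate 2.

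Many hairpins differed between the libraries, and all tests of explanations for this were chosen after the result was seen. Counting error was not settled by simulation: libraries drawn with no difference gave 0 calls by the binomial test (11 of 318 at an unadjusted p under 0.05), but they shared its noise model and took PCR copies as independent. A difference in transcription as the whole cause was not settled either: 43 of 89 pairs of neighbouring hairpins on 1 strand had unequal ratios by Fisher's exact test and at least 1.5-fold, a test with the same noise model. Sequence-dependent capture may contribute, but cannot be told apart from a difference between the animals: distant hairpins sharing 14 to 19 nt had correlated ratios (r = 0.298, permutation p = 0.0474), yet this cutoff was picked after 4 had been looked at (12, 13, 14 and 16 nt), which gave r from 0.0940 to 0.442. The excess over neighbours was tested in 2 ways, first with pairs sharing 20 nt or more included (0.335, permutation p = 0.0361) and then without them (0.139, permutation p = 0.439), so the evidence stays open.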
